A study of Mus musculus with 5 samples.

How the data were processed

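Total RNA of whole blood from female F1 mice was measured in 5 samples, 2 of the AKR/J by FVB/NJ cross and 3 of the DBA/2J by FVB/NJ cross. Per the labels' protocols, blood was taken by cardiac puncture after the animals were killed under Avertin anaesthesia, RNA was extracted with Trizol, and the RNA was amplified with a kit of 2 cycles and labelled with biotin by the array maker's protocol. Samples were grouped by the cross named in their source label, and the replicate numbers came from their titles.

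The authors deposited 1 normalized value per probe set and array, and these values were taken as log2 expression. That base was inferred from the range of the values, which ran from 1.29 to 14.8, since no label or header states it. Per the submitters' processing notes, MAS5 and RMA were used, without versions, and the sources used here do not say which of them gave the deposited values. The background correction and the normalization between arrays are thus not known, and low values near 2 to 3 have no stated limit of detection. A method that compresses low signals would make fold changes of dim probe sets too small.

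The table held 45101 probe sets, 64 of them array controls, which were left out of the tests. The platform annotation used here gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211. The symbols of 34754 were looked up by gene identifier in a table of mouse genes of assembly GRCm38.p6, which changed 0 of them. Probe sets with several symbols were tested but not named. No column of values lay outside the 5 samples. The reference table was used for names and for the order of genes along chromosomes, and no coordinates are given because the sources used here do not name the build behind the array annotation.

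The choices in this paragraph, the gene lists and the rule for named genes were fixed before the data were examined. Probe sets were tested when their mean over the 5 arrays was at or above the median of all non-control probe sets, 2.51, which left 22519. The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend and without robust estimation), with the cross as the only term, 3 residual degrees of freedom and a two-sided moderated test. The threshold was a Benjamini-Hochberg adjusted p below 0.05. For 2 arrays against 3, an exact permutation test cannot give a p under 0.1, so single values were not tested that way. Error terms after a difference are limma's moderated standard errors.

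There were 25 gene lists: blood cell types, other cells that a cardiac puncture can bring, pathways, known strain variants, a sex check and housekeeping controls. Of 788 entries, 667 had a probe set with 1 symbol, 4 of them through an older symbol. Each gene was represented by its tested probe set with the highest mean. The 22 lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and repeated with the correlation estimated from the data and with fry, a rotation test of whether a list's genes move on balance in 1 direction. Members past the threshold were counted over all genes tested and adjusted over the list alone.

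The genes named in the text followed a rule. Up to 12 genes per direction with the largest change were to be taken among those past the threshold whose groups did not overlap. Since none passed, the 6 with the smallest p in each direction were named, again only among genes whose groups did not overlap. Named as well were up to 4 members with the smallest p in each list and the genes of the strain, sex and housekeeping lists. Agreement between probe sets of 1 gene and the grouping of genes along chromosomes were planned for genes past the threshold. As none passed, they were computed for genes at an unadjusted p below 0.01, with exact binomial intervals and, for the grouping, a one-sided permutation test.

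The alternatives were quantile normalization, median centring and cyclic loess normalization of the deposited values, no filter or a filter at the 75th percentile, no variance trend, robust variance estimation, array weights, the replicate number as a block, each array left out in turn, other thresholds, and a test without moderation. A planned floor for linear values did not apply to log2 values. Before use, the limma and camera steps were tested on simulated data made from the real means and variances: over 10 runs, limma called 424 of 710 probe sets changed by a fold of 2 and 132 of 223190 unchanged ones. Camera on 12421 genes called 0 lists in 10 runs without a shift, and called a list of 22 genes shifted by 0.5 in all 10 runs, or in 3 runs with an estimated correlation. The simulated noise was independent between genes. These runs therefore cannot show how often camera calls a list by mistake where its members are correlated. Python 3.11.15 with pandas 2.3.3 prepared the annotation, and matplotlib 3.10.9 drew the plots.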

Results

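Whole blood of adult female mice of 2 first-generation crosses was profiled on Affymetrix expression arrays, 1 array per sample. Both crosses share the FVB/NJ strain and differ in the other parent, which was AKR/J in 2 samples (AKRxFVB F1) and DBA/2J in 3 samples (DBAxFVB F1). The study asked which genes differ in basal expression in blood between the genotypes. The values of 45101 probe sets were on a log2 scale, and the median over non-control probe sets lay between 2.49 and 2.55 on the 5 arrays. The number of arrays limits the precision of every value below. The labels do not say whether the samples of a cross came from separate animals. The limma p-values thus rest only on the spread between these samples, which may be technical. At the preset correlation camera compares a list's genes with all other genes, so its p-values are not a measure of the spread between samples. Differences are given as DBAxFVB F1 minus AKRxFVB F1 on the log2 scale.

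No single gene passed the test between the crosses, and the genes nearest to the threshold were mostly lower in DBAxFVB F1 blood. Foxp1, a forkhead transcription factor, read 6.07 ± 0.16 (SD, n = 2) in AKRxFVB F1 and 3.94 ± 0.27 (SD, n = 3) in DBAxFVB F1, a difference of -2.13 ± 0.25 (SE). Vapa, a membrane protein of the endoplasmic reticulum, differed by -1.94 ± 0.24, and Rbbp7, a histone-binding subunit of chromatin complexes, by -1.71 ± 0.22. The differences were -1.39 ± 0.17 for Wdr61, -1.31 ± 0.16 for the histone acetyltransferase Ep300 and -1.21 ± 0.14 for the cohesin subunit Rad21, whose AKRxFVB F1 means were 3.86, 3.74 and 3.33. Their DBAxFVB F1 means, 2.475, 2.43 and 2.11, lay below the array medians, near the lower end of the scale. Each gene is given by its probe set with the smallest p. The limma adjusted p was 0.131 for all 6. In each of them, every AKRxFVB F1 array lay above every DBAxFVB F1 array, which the selection of these genes required.

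In the other direction, the differences of the genes with the smallest p were between 0.69 and 0.94. Ppp1r35 read 3.10 ± 0.25 (SD, n = 2) against 4.04 ± 0.19 (SD, n = 3), a difference of 0.94 ± 0.20 (SE). Iqcf4 differed by 0.85 ± 0.14, with the smallest limma adjusted p on this side, 0.144. Ampd2, an AMP deaminase, differed by 0.78 ± 0.17, the antisense transcript Sox6os by 0.71 ± 0.14, and Cdrt4 and the nucleotidase gene Entpd8 by 0.69 each. Their limma adjusted p ranged up to 0.195, so none of the 12 genes passed. The AKRxFVB F1 means of Iqcf4, Sox6os and Entpd8 lay below the array medians, at 2.34, 2.10 and 2.17. Those of Cdrt4 and Ampd2 were 2.735 and 2.94, so most of these differences lie near the lower end of the scale.

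**Figure D1:**
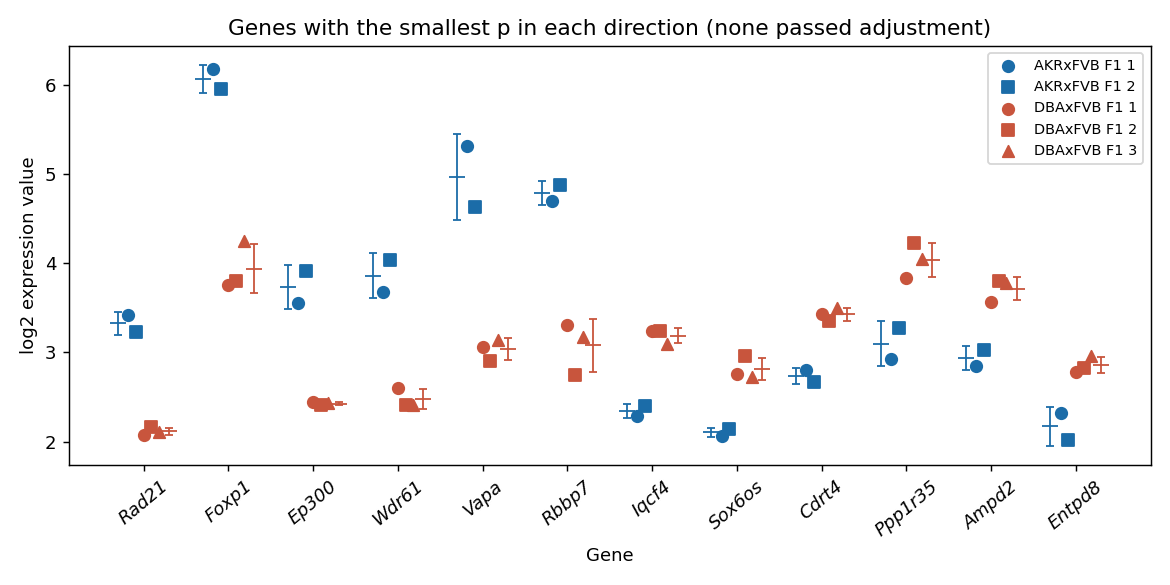
log2 expression values (vertical axis) of the 6 genes with the smallest p in each direction (horizontal axis), with a point per array, blue for AKRxFVB F1 (n = 2) and red for DBAxFVB F1 (n = 3), and a bar for each cross's mean with its SD. The 12 genes were selected among those whose groups do not overlap, Foxp1 has the largest difference (-2.13), and none passed the adjusted threshold.

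Of 22519 probe sets tested, which stood for 12421 named genes, limma called 0 probe sets and 0 genes at an adjusted p below 0.05, and the smallest adjusted p was 0.131. At an unadjusted p below 0.05 there were 2337 probe sets, 808 higher and 1529 lower in DBAxFVB F1, where 1126 would be expected if probe sets were independent. The lower side made up 65.4% of them, against 77% after median centring and 78.9% after cyclic loess normalization. It made up 59.7% without a filter and 59.3% without DBAxFVB F1 array 1. A fold of 2 or more was seen for 530 probe sets lower and 14 higher. The groups did not overlap for 28.9% of probe sets, against 20% by chance, and of these 6510 probe sets more were higher in DBAxFVB F1 (3683) than lower (2827). Without AKRxFVB F1 array 1 the count at an unadjusted p below 0.05 was 1271.

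B cell genes fell as a list in DBAxFVB F1 blood. Of 25 tested members, 24 were lower and 11 of those had an unadjusted p below 0.05, and the list median was -0.63 (camera adjusted p = 1.1e-09). The call was lost with an estimated correlation (adjusted p = 0.656). Members past the threshold numbered 0 over all genes tested and 5 adjusted over the list alone. Ms4a1, which encodes the B cell surface antigen CD20, read 7.50 ± 0.75 (SD, n = 2) in AKRxFVB F1 and 5.55 ± 0.56 (SD, n = 3) in DBAxFVB F1. The differences were -1.78 ± 0.45 (SE) for the transcription factor gene Spib, -1.64 ± 0.40 for the light chain gene Iglv1 and -1.38 ± 0.38 for the B cell transcriptional repressor Bach2, and none of these genes passed over all genes. Bach2 ranged from -2.06 to -0.69 and Iglv1 from -2.29 to -0.98 with 1 array left out. Relative to the mean of all arrays, the list median was 1.12 on AKRxFVB F1 array 1 and -0.02 on array 2, and -0.60, -0.53 and 0.12 on the DBAxFVB F1 arrays. The list median was -0.36 without AKRxFVB F1 array 1, -1.37 without array 2, and -1.20 with the filter at the 75th percentile.

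T cell genes also fell as a list, with 22 of 29 tested members lower and a list median of -0.23 (camera adjusted p = 0.000655, or adjusted p = 0.656 with an estimated correlation). Among their values, the surface antigen gene Cd2 differed by -1.13 ± 0.30 (SE), the T cell receptor complex gene Cd3d by -1.38 ± 0.38, the interleukin receptor gene Il7r by -0.75 ± 0.30 and Thy1 by -0.71 ± 0.20. Cd2 ranged from -1.57 to -0.68 and Thy1 from -1 to -0.41 with 1 array left out. No member passed over all genes or adjusted over the list alone. Relative to the mean of all arrays, the T cell median was 0.09 and 0.23 on the AKRxFVB F1 arrays. On the DBAxFVB F1 arrays it was 0.12, -0.13 and -0.14, so the groups overlapped. Without AKRxFVB F1 array 2 the list median was -0.08 and the call was lost (adjusted p = 0.109), and it was -0.34 without AKRxFVB F1 array 1 and -0.12 without DBAxFVB F1 array 3 or array 2. The median was -0.08 without a filter or with all probe sets as members, and -0.14 with array weights. Natural killer and cytotoxic genes did not pass (median 0.06, 12 of 19 higher, camera adjusted p = 0.778), with Txk at 0.32 ± 0.16, Nkg7 at -0.50 ± 0.27, Ccl5 at -0.31 ± 0.18 and Cd244a at 0.25 ± 0.16. Nkg7 ranged from -0.98 to -0.03, Ccl5 from -0.52 to -0.11 and Cd244a from 0.13 to 0.37 with 1 array left out.

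Antigen presentation genes of both classes fell as lists. The class I list, with antigen processing genes, had a median of -0.36 and 12 of 15 members lower (camera adjusted p = 0.0014, or adjusted p = 0.467 with an estimated correlation). Its values included H2-K1 at -0.97 ± 0.37 (SE), H2-D1 at -0.91 ± 0.31, the chaperone gene Calr at -0.90 ± 0.30 and the immunoproteasome gene Psmb8 at -0.60 ± 0.19. The class II list had a median of -0.38 and 9 of 11 members lower (camera adjusted p = 0.0105, or adjusted p = 0.656 with an estimated correlation). Cd74, the invariant chain of class II molecules, differed by -1.50 ± 0.54, H2-Ob by -1.18 ± 0.39, H2-Aa by -1.12 ± 0.53 and H2-Oa by -0.38 ± 0.18. With 1 array left out, Cd74 ranged from -2.19 to -0.81, H2-Ob from -1.86 to -0.49 and H2-Aa from -2.01 to -0.22, and after quantile normalization H2-Aa was at -0.52, H2-D1 at -0.34 and H2-K1 at -0.49. No member of either list passed over all genes or adjusted over the list alone. The class I median was -0.13 after quantile normalization, -0.20 after cyclic loess normalization, -0.21 without AKRxFVB F1 array 2 and -0.17 without DBAxFVB F1 array 3. The class II median was -0.07 without AKRxFVB F1 array 1 (adjusted p = 0.651), -0.34 without DBAxFVB F1 array 1 (adjusted p = 0.119), -0.28 after quantile normalization (adjusted p = 0.203) and -0.44 after cyclic loess normalization (adjusted p = 0.111), and in these settings the call was lost. It was -1.09 without AKRxFVB F1 array 2 and -0.61 without DBAxFVB F1 array 3. Relative to the mean of all arrays, the class II median was 0.86 and -0.12 on the AKRxFVB F1 arrays. On the DBAxFVB F1 arrays it was -0.345, -0.24 and 0.16, so the groups overlapped.

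Interferon response genes did not pass as a list (median -0.05, 18 of 32 lower, camera adjusted p = 0.275). Ifi35 had the smallest p among them, with a difference of -1.29 ± 0.32 (SE), and the guanylate-binding protein gene Gbp2, Trim30a and Parp14 differed by -0.44 ± 0.17, -0.45 ± 0.19 and -0.44 ± 0.19. None passed over all genes or adjusted over the list alone.

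Ribosomal protein genes fell together and had the smallest p of any list in the camera test of the deposited values at the preset correlation. Of 36 tested members, 35 were lower in DBAxFVB F1, 14 of them at an unadjusted p below 0.05, and the list median was -0.82 (camera adjusted p = 6.13e-13, or adjusted p = 0.58 with an estimated correlation). Rpl22 read 9.36 ± 0.51 (SD, n = 2) against 7.89 ± 0.19 (SD, n = 3), and Rps18 read 8.03 ± 0.31 against 6.60 ± 0.50. Rps20 differed by -1.19 ± 0.39 (SE) and Rpl6 by -1.18 ± 0.39. Oxidative phosphorylation genes of the mitochondrial respiratory chain had 48 of 57 members lower and a median of -0.33 (camera adjusted p = 2.11e-06, or adjusted p = 0.467 with an estimated correlation). The respiratory complex gene Ndufa6 differed by -0.88 ± 0.21, the ATP synthase gene Atp5g3 by -1.43 ± 0.40, Uqcrb by -1.20 ± 0.36 and Atp5c1 by -0.90 ± 0.31. No member of these lists passed over all genes or adjusted over the list alone. After quantile normalization the ribosomal median was -0.29 and that of oxidative phosphorylation -0.07, where the second call was lost (adjusted p = 0.0662). After cyclic loess normalization the medians were -0.39 and -0.15, and that of oxidative phosphorylation was -0.11 without DBAxFVB F1 array 3 and -0.21 with array weights.

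The signal of bright probe sets differed between the arrays in the same direction as these lists. Probe sets with a mean log2 value of 8 to 10 had a median difference of -0.56 between the crosses and those of 10 to 15 one of -0.30, against 0.07 for those with a mean of 2.5 to 3. On DBAxFVB F1 array 3, those of 8 to 10 lay -0.91 and those of 10 to 15 lay -0.61 from their mean over the arrays. The 18 hybridisation control probe sets, which detect labelled transcripts added before hybridisation, had a median of 7.99 on that array and between 10.01 and 10.12 on the others. The 3-prime minus 5-prime difference, a sign of RNA quality, was highest on that array as well, at 1.32 for Actb and 1.33 for Gapdh, against 0.82 and 0.62 on array 1 and 0.68 and 0.58 on array 2 of that cross. It was 1.22 and 1.04 on AKRxFVB F1 array 1 and 1.03 and 0.73 on array 2. The median level of the ribosomal protein list was 8.77, that of the B cell list 4.07. Housekeeping genes lay lower in DBAxFVB F1 as well, with Hprt at -1.13 ± 0.25 (SE), Pgk1 at -0.96 ± 0.29, Ywhaz at -0.80 ± 0.68 and Actb at -0.66 ± 0.37. After quantile normalization Actb was at -0.15 and Ywhaz at -0.37, and after cyclic loess normalization at -0.08 and -0.43. Ywhaz ranged from -1.30 to -0.11 with 1 array left out. Of the 4 genes, 0 passed over all genes and 2 passed adjusted over the list alone, and Tbp had a mean below the filter.

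**Figure D2:**
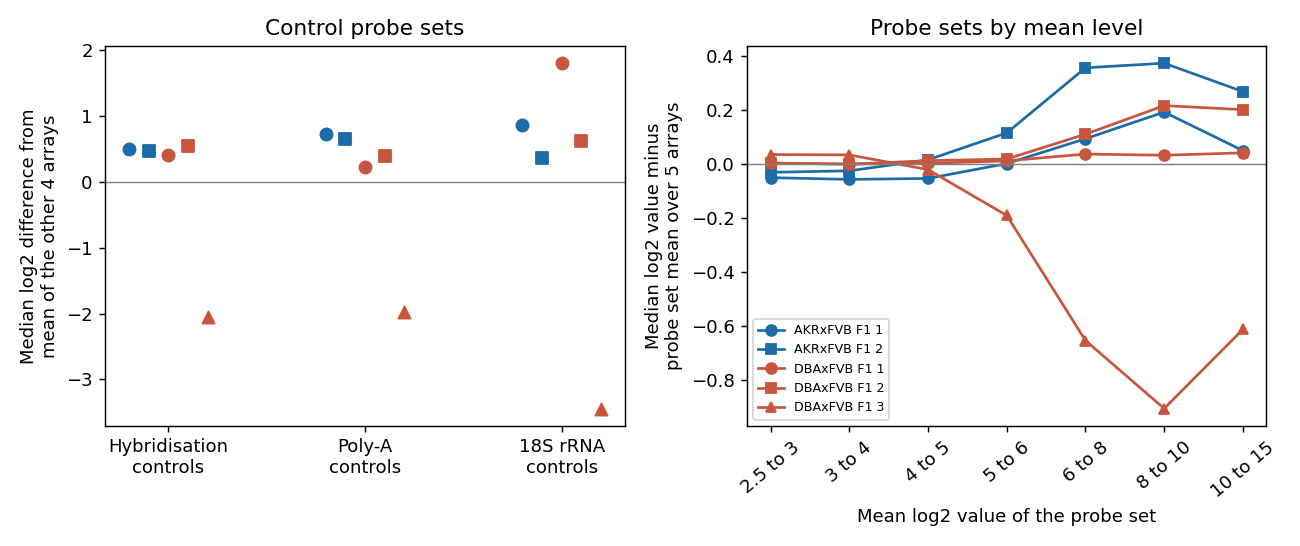
Left, median log2 difference of the hybridisation, poly-A and 18S ribosomal RNA control probe sets (horizontal axis) on each array from the mean of the other 4 arrays (vertical axis), and right, median log2 value minus the probe set's mean over 5 arrays (vertical axis) by bins of mean log2 value (horizontal axis), with a point per array, blue for AKRxFVB F1 and red for DBAxFVB F1. DBAxFVB F1 array 3 lies at -2.05 for the hybridisation controls and at -0.91 for probe sets of mean 8 to 10.

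Proliferation and stress genes did not pass as lists. Cdt1, which licenses DNA replication, read 5.55 ± 0.42 (SD, n = 2) in AKRxFVB F1 and 4.03 ± 0.27 (SD, n = 3) in DBAxFVB F1 (limma adjusted p = 0.152), and the replicative helicase gene Mcm4 differed by -0.83 ± 0.19 (SE). The replication clamp gene Pcna differed by -1.07 ± 0.39 and the cyclin-dependent kinase gene Cdk1, in the other direction, by 0.42 ± 0.16. Adjusted over the list alone, 2 cell cycle members passed, and 0 over all genes. The cell cycle list had 16 of 32 members higher and a median of -0.00111 (camera adjusted p = 0.319). Among immediate early and heat shock genes (median 0.05, 17 of 29 higher, camera adjusted p = 0.319), the chaperone genes Hspa8, Hsph1 and Hspd1 differed by -1.15 ± 0.30, -0.80 ± 0.22 and -1.23 ± 0.40, the transcription factor gene Klf2 by -0.97 ± 0.38, and none passed. For this list the mean over members was -0.08, of the opposite sign to the median, and without DBAxFVB F1 array 3 the median was -0.02 and the list passed at the preset correlation (adjusted p = 0.0106) but not with an estimated one (adjusted p = 0.437 with an estimated correlation). With all probe sets as members its median was -0.05 and it passed at the preset correlation (adjusted p = 0.0132).

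Myeloid and erythroid lists did not pass. Neutrophil genes had a median of 0.16 (16 of 22 higher, camera adjusted p = 0.275), with the receptor gene Csf3r at 0.42 ± 0.17 (SE), Hdc, the enzyme that makes histamine, at 0.68 ± 0.38, the interleukin gene Il1b at 0.32 ± 0.18 and Lrg1 at 0.50 ± 0.28. At the preset correlation they passed without AKRxFVB F1 array 1 (median 0.20, adjusted p = 0.0271). Monocyte genes had a median of -0.03 (11 of 21 lower, camera adjusted p = 0.286), yet the cathepsin gene Ctss differed by -1.49 ± 0.50, Cybb, a subunit of the phagocyte oxidase, by -1.37 ± 0.46, Ms4a6b by -1.27 ± 0.43 and the lysozyme gene Lyz1 by -0.88 ± 0.43, none of which passed. Ctss ranged from -2.04 to -0.93 and Cybb from -1.86 to -0.87 with 1 array left out. Quantile normalization gave Ctss -0.91 and Lyz1 -0.28. Without DBAxFVB F1 array 3 the monocyte median was -0.10 (adjusted p = 0.00604 at the preset correlation, or adjusted p = 0.437 with an estimated correlation). Dendritic cell genes had a median of 0.02 and a mean of the opposite sign, -0.12 (camera adjusted p = 0.53), with Ly6d at -1.54 ± 0.62, the cystatin gene Cst3 at -0.67 ± 0.30, the transcription factor gene Tcf4 at -0.78 ± 0.39 and Klk1 at 0.65 ± 0.37. Cst3 was at -0.12 after quantile normalization. Ly6d ranged from -2.38 to -0.70, Tcf4 from -1.45 to -0.115 and Klk1 from 0.32 to 0.91 with 1 array left out. Eosinophil, basophil and mast cell genes had a median of 0.11 over 8 members (camera adjusted p = 0.778), with Gata2 at -0.45 ± 0.25, Hdc as given above, and the mast cell protease genes Cpa3 at -0.51 ± 0.38 and Tpsab1 at 0.21 ± 0.20. Erythroid genes had a median of -0.01 over 29 members (camera adjusted p = 0.513), and Hba-a2, an alpha globin gene, read 5.79 ± 0.10 (SD, n = 2) against 4.86 ± 1.30 (SD, n = 3), a difference that ranged from -1.43 to -0.20 with 1 array left out. The carbonic anhydrase gene Car1 differed by 0.33 ± 0.22 (SE), Hba-a1 by 0.18 ± 0.14 and the spectrin gene Sptb by -0.34 ± 0.27. The means of Hba-a1 were 2.45 in AKRxFVB F1 and 2.63 in DBAxFVB F1, and those of Car1 2.58 and 2.905. These lie near the array medians, so the 2 probe sets say little about either gene. The globin entries Hbb-b1, Hbb-bs and Hbb-bt had no probe set with 1 symbol. The erythroid list passed at the preset correlation without DBAxFVB F1 array 2 (median -0.16, adjusted p = 0.0238).

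Platelet and megakaryocyte genes varied more between the arrays of a cross than between the crosses. The list had 27 of 34 members lower, a median of -0.46 and a camera adjusted p of 0.147, so it did not pass. Relative to the mean of all arrays its median was -0.30 and 0.85 on the AKRxFVB F1 arrays and 0.38, 0.30 and -1.29 on the DBAxFVB F1 arrays. At the preset correlation it passed without AKRxFVB F1 array 1 (median -1.01, adjusted p = 0.000138), without DBAxFVB F1 array 1 (median -0.69, adjusted p = 0.0116) and without array 2 of that cross (median -0.72, adjusted p = 0.00498), and its median was 0.13 without array 3. By the size of p its first members were the collagen receptor gene Gp6 at 0.54 ± 0.26 (SE), Pdgfb at 0.31 ± 0.17, the transcription factor gene Gata2 at -0.45 ± 0.25 and the coagulation factor gene F10 at 0.29 ± 0.23.

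**Figure D3:**
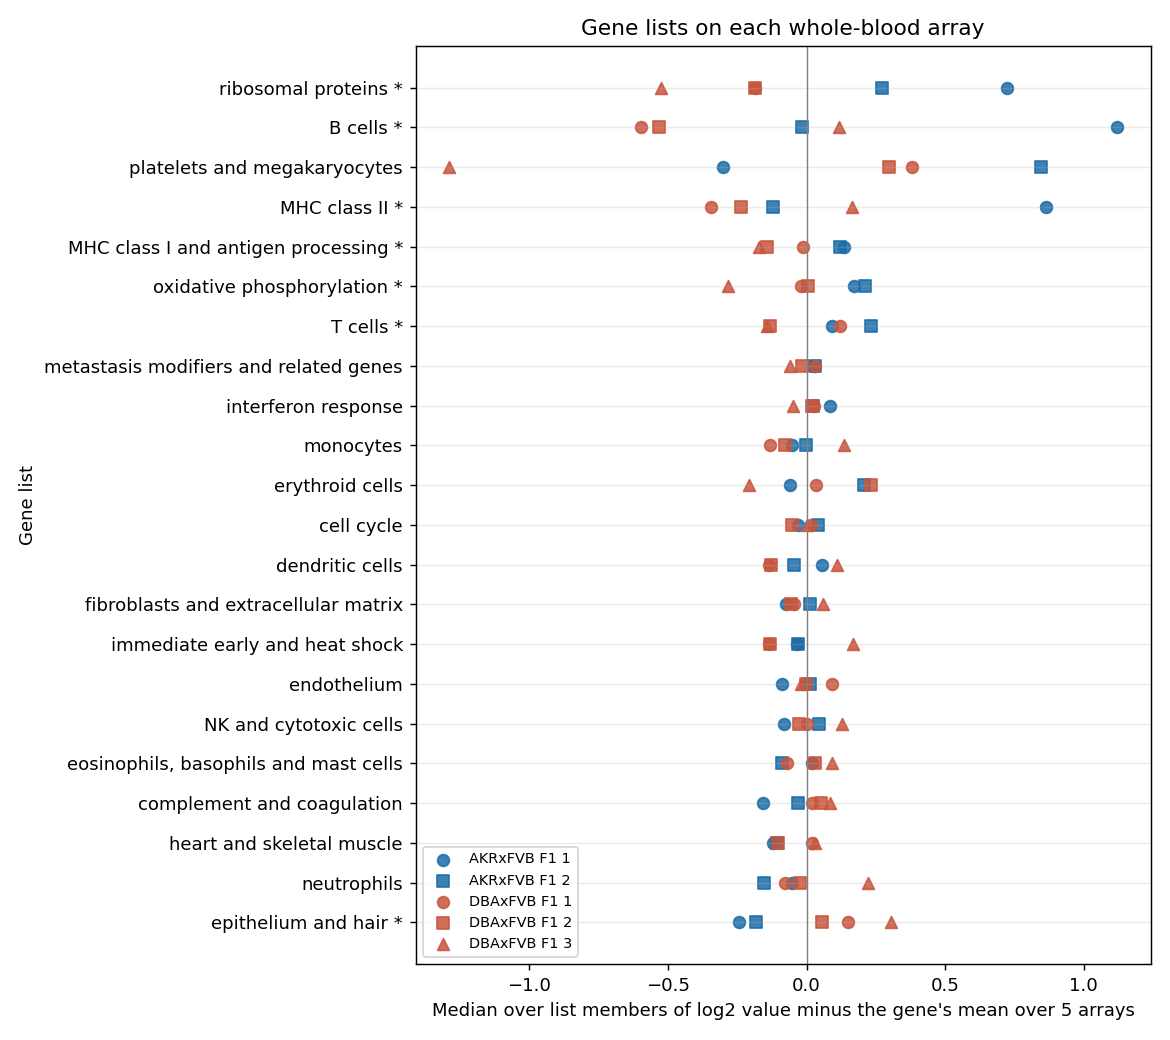
Median over the members of each gene list (vertical axis) of the log2 value minus the gene's mean over 5 arrays (horizontal axis), with a point per array, blue for AKRxFVB F1 and red for DBAxFVB F1. An asterisk marks the 7 lists with a camera adjusted p below 0.05 at the preset correlation, none of which passed with an estimated correlation, and the B cell medians run from -0.60 to 1.12 and the platelet medians from -1.29 to 0.85.

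Genes of heart, vessel and other solid tissues had median levels between 3.23 and 3.37, near the lower end of the scale. Epithelium and hair genes rose as a list, with 11 of 12 members higher and a median of 0.39 (camera adjusted p = 0.00553, or adjusted p = 0.467 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The claudin gene Cldn3 read 4.26 ± 0.29 (SD, n = 2) against 5.02 ± 0.42 (SD, n = 3), and the keratin genes Krt8, Krt19 and Krt14 differed by 0.53 ± 0.18 (SE), 0.42 ± 0.18 and 0.42 ± 0.21. With all probe sets as members the list median was 0.25. Heart and skeletal muscle genes did not pass (median 0.14, 14 of 21 higher, camera adjusted p = 0.313), with the actin gene Actc1 at 0.75 ± 0.27, the myosin light chain gene Myl2 at 0.78 ± 0.34, Acta1 at -0.72 ± 0.24 and the myoglobin gene Mb at 0.42 ± 0.22. Endothelial genes had a median of 0.06 (camera adjusted p = 0.53), with Mmrn2 at 1.09 ± 0.41, Cldn5 at 0.71 ± 0.22, Nos3 at 0.24 ± 0.15 and Cdh5 at -0.20 ± 0.15. Fibroblast and extracellular matrix genes had a median of 0.02 (camera adjusted p = 0.724), with Sparc at 0.57 ± 0.29, Timp1 at 0.69 ± 0.37, Pdgfra at 0.27 ± 0.17 and Pdgfrb at -0.21 ± 0.16.

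Genes that modify metastasis in mice or humans did not pass as a list (median -0.11, 13 of 20 lower, camera adjusted p = 0.334). Arid4b, a chromatin-binding protein, read 3.78 ± 0.40 (SD, n = 2) in AKRxFVB F1 and 2.45 ± 0.17 (SD, n = 3) in DBAxFVB F1 (limma adjusted p = 0.131) and was the 1 member that passed adjusted over the list alone. Mtss1 differed by -0.78 ± 0.25 (SE), Brms1 by 0.57 ± 0.22 and Nfix by 0.49 ± 0.20. Complement and coagulation genes had a median of 0.12 over 17 members (camera adjusted p = 0.427), with Plau at 0.30 ± 0.14, C1qa at 0.54 ± 0.30, C3ar1 at 0.29 ± 0.16 and Cd55 at -0.36 ± 0.21.

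Genes with known strain variants were tested in 4 cases, too few for a list test, and 1 of these passed adjusted over the list alone. Thy1, whose protein has a different allele in AKR/J, is given above, Gpnmb differed by 0.29 ± 0.19 (SE) and Tyrp1 by 0.28 ± 0.33. H2-Ea, a class II gene that some mouse haplotypes do not express, read 8.06 and 5.91 on the AKRxFVB F1 arrays and 5.73, 6.76 and 8.04 on the DBAxFVB F1 arrays. The X-linked Xist, expressed in females, read between 4.97 and 6.91 on all 5 arrays and differed by -1.28 ± 0.38 (limma adjusted p = 0.311), while the Y-linked Eif2s3y, Kdm5d and Uty read between 1.69 and 2.56. Xist was the 1 tested gene of the sex check, so it alone passed adjusted over the list alone, and 0 passed over all genes. Klrd1, which DBA/2J lacks, had a mean below the filter and read 2.68 ± 0.49 (SD, n = 2) against 2.05 ± 0.17 (SD, n = 3). Myo5a, Hc and Pde6b were below the filter as well.

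None of the 7 lists that passed at the preset correlation passed with an estimated correlation, where the smallest adjusted p was 0.467, or with fry, where it was 0.11. The estimated correlation was run with all arrays and without DBAxFVB F1 array 3 only. With all arrays it was 0.571 for B cells, 0.542 for class II, 0.397 for ribosomal proteins and 0.206 for T cells, against the preset 0.01. It was 0.0562 for class I, 0.0246 for oxidative phosphorylation and, below the preset, 0.00563 for epithelium and hair. A higher correlation thus does not explain why the call of epithelium and hair was lost. Over all alternatives the adjusted p ran from 9.58e-06 to 0.656 for T cells, 1.49e-05 to 0.656 for class II and 1.81e-08 to 0.467 for oxidative phosphorylation. Among lists that had not passed, it ran from 0.0271 to 0.893 for neutrophils, 0.00604 to 0.787 for monocytes, 0.0238 to 0.923 for erythroid genes, 0.000138 to 0.91 for platelets and 0.00861 to 0.869 for immediate early and heat shock genes. Tested on simulated data for this comparison, with 200 of 22519 probe sets changed in each of 10 runs, limma called 59.7% of probe sets changed by a fold of 2, 96.2% at a fold of 4 and 99.8% at a fold of 8. The simulated noise was independent between probe sets and drawn from the moderated variances. These shares thus need not hold for the real arrays, where 544 probe sets had a fold of 2 or more and 0 were called.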

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

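The counts at an unadjusted p, the checks at an unadjusted p below 0.01 and the estimated correlation without DBAxFVB F1 array 3 were chosen after seeing the data. The 0 calls of probe sets and genes held under every alternative run, with smallest adjusted p between 0.0639 and 0.57. The count at an unadjusted p below 0.05 was 3880 without a filter and 1299 with the filter at the 75th percentile, which test more and fewer probe sets, and 1271 to 2514 when 1 array was left out. Leaving out an array of AKRxFVB F1 leaves 1, which is then assumed to vary like the other cross. The lists past the threshold numbered 5 to 9, except for 0 with an estimated correlation (smallest adjusted p 0.467), 0 with fry (0.11) and 0 with an estimated correlation and without DBAxFVB F1 array 3 (0.437). For epithelium and hair the estimated correlation, 0.00563, lay below the preset 0.01. Its unadjusted camera p still rose from 0.00151 to 0.0477, so a higher correlation does not explain the loss of that call. The cause was otherwise not tested. The first and second of these settings change only the p-value and cannot move a median. The medians were -0.63 for B cells, -0.23 for T cells, 0.39 for epithelium and hair, -0.36 for class I, -0.38 for class II, -0.82 for ribosomal proteins and -0.33 for oxidative phosphorylation. Without DBAxFVB F1 array 3 they were -0.94, -0.12, 0.31, -0.17, -0.61, -0.65 and -0.11, with erythroid genes at 0.0919, platelets at 0.13, dendritic cells at -0.0345 and immediate early and heat shock genes at -0.0197. With the replicate number as a block, 0 probe sets and 9 lists passed, and the same 4 reversed medians were found, with Tyrp1 at -0.0126. The block gives DBAxFVB F1 array 3 a term of its own. The numbers were not taken to pair samples, since the titles do not say that they do. Deviations of same-numbered arrays correlated at -0.26 and 0.17. With 2 AKRxFVB F1 arrays, the deviations from their mean mirror each other, so these correlations can neither show nor exclude pairing. Calls were lost after quantile normalization for class II (-0.28) and oxidative phosphorylation (-0.0673) and after cyclic loess normalization for class II (-0.44). With 1 array left out, T cells ranged from -0.338 to -0.0815 and class II from -1.09 to -0.0674, and the cause was not tested. Lists that had not passed changed sign as follows, with causes not tested. After quantile normalization erythroid genes were at 0.11, monocytes at 0.0687, dendritic cells at -0.032 and cell cycle at 0.0215, with the gene H2-Ea at 0.37. Median centring gave dendritic cells -0.0266 and fibroblasts -0.0211. Cyclic loess gave erythroid genes 0.13, dendritic cells -0.0476, fibroblasts -0.044 and H2-Ea 0.14. Without a filter cell cycle was at 0.0337, and with array weights erythroid genes were at 0.0387 and dendritic cells at -0.0161. With all probe sets as members, dendritic cells were at -0.0149, cell cycle at 0.0338 and immediate early and heat shock genes at -0.0472. With 1 array left out, the medians ranged from -0.221 to 0.0919 for erythroid genes, -0.095 to 0.0404 for monocytes, -0.0326 to 0.126 for natural killer genes, -1.01 to 0.205 for platelets, -0.0696 to 0.109 for dendritic cells, -0.0725 to 0.0345 for cell cycle and -0.0197 to 0.108 for immediate early and heat shock genes. For single genes they ranged from -1.08 to 0.0701 for Cpa3, -0.0754 to 0.632 for Tyrp1 and -1.22 to 0.927 for H2-Ea. Over 106 probe sets of named genes, 1444 of 1452 recomputed differences kept their direction and 0 passed. Other filters, no variance trend and robust variance estimation do not alter a difference, so a part of these differences could not change direction. The size moved by over 1.5 times for 0 of the 12 genes with the smallest p and for 51 of 94 other named genes with 1 array left out, 20 after quantile normalization, 10 after cyclic loess and 0 after median centring. The 12 genes were selected on these same arrays for a small p and groups that do not overlap. That selection favours stable differences, so their stability is no separate support. Robust variance estimation has no counterpart in camera, and the planned floor was not run. At the adjusted threshold, agreement between probe sets and neighbouring genes had no value.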

Other observations

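The tests of the weak array as a cause, RNA ends, B cell number, probe set agreement and the count at an unadjusted p were chosen only after the result was seen, as was the unadjusted p for neighbouring genes. The genes named in the next 2 paragraphs were chosen after their values were seen, and the differences there are values without a test.

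The 2 AKRxFVB F1 samples differed in B cell, class II, ribosomal protein and platelet genes. B cell genes lay higher on array 1, by a list median of 1.03 with 24 of 25 members higher, and so did class II genes (1.04, 10 of 11). Cd79b, part of the B cell receptor, read 6.64 against 4.85, and the coactivator gene Pou2af1 read 7.69 against 6.07. Ribosomal protein genes lay 0.49 higher on array 1 (32 of 36 members), and T cell genes lay the other way, at -0.23 with 8 of 29 members higher. Platelet genes lay at -1.06 on array 1 relative to array 2, with 3 of 34 members higher. Pf4, a platelet chemokine, read 9.58 against 11.3, and the coagulation factor gene F5 read 5.52 against 7.58. Of 12421 genes, 112 were higher and 187 lower on array 1 by a fold of 2 or more, against 36 and 27 between arrays 1 and 2 of DBAxFVB F1.

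DBAxFVB F1 array 3 differed from the other two of its cross in immediate early, platelet, erythroid, ribosomal protein and B cell genes, and 256 genes were higher and 511 lower on it by a fold of 2 or more than the mean of those arrays. Immediate early and heat shock genes lay 0.45 higher in the median, with 22 of 29 members higher. Dusp1 read 6.56 against 3.23 and 4.10, Fos 5.13 against 2.66 and 3.02, and Egr1 4.73 against 2.32 and 3.16. Fn1, a gene of the extracellular matrix, read 7.60 against 4.70 and 5.91, and Dcn 6.05 against 3.97 and 4.33, while the list of fibroblast and extracellular matrix genes lay 0.07 higher in the median, with 17 of 29 members higher. Platelet genes lay at -1.66 in the median, with Rgs18 at 6.88 against 9.99 and 9.58 and Tubb1 at 6.84 against 9.11 and 9.10. Erythroid genes lay at -0.35 with 1 of 29 members higher, and ribosomal protein genes at -0.33 with 10 of 36 higher. B cell genes lay 0.77 higher, with 20 of 25 members higher. The 3-prime minus 5-prime differences on this array were 1.32 for Actb and 1.33 for Gapdh, against 0.82 and 0.62 on array 1 and 0.68 and 0.58 on array 2.

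The 6 lists lower in DBAxFVB F1 were weighed against compression of bright probe sets, with random lists matched on mean level. The ribosomal median of -0.82 lay at the 0.01 percentile, the smallest that 10000 lists can give. The random lists had a median of -0.46 and a 2.5th percentile of -0.55, so equally bright genes were lower too (bootstrap interval of the ribosomal median -0.94 to -0.71). That of B cells lay at the same percentile (random median 0.05, 2.5th percentile -0.10, bootstrap -1.38 to -0.33). The bootstrap resampled genes as if independent, so its intervals do not measure the spread between samples. For these 2 lists the values argue against compression as the whole cause, while for class II compression may account for the shift (percentile 7.43). It stays open for oxidative phosphorylation (2.15), class I (0.62) and T cells (0.03), whose bootstrap intervals reach into the random range. Without the weak array 3 all 6 lists passed camera at the preset correlation and 0 with an estimated one (adjusted p from 0.437 to 0.626). The preset calls cannot decide on that array as a cause. They do not measure the spread between samples, and other splits of the arrays gave up to 8 lists. Without that array the medians stayed negative, at -0.94 for B cells, -0.65 for ribosomal proteins, -0.61 for class II, -0.17 for class I, -0.12 for T cells and -0.11 for oxidative phosphorylation. That array alone thus does not set the direction, while its part in the size of these shifts stays open. For RNA quality, 2 of 3 DBAxFVB F1 arrays had smaller 3-prime minus 5-prime differences of Actb and Gapdh than both AKRxFVB F1 arrays, which argues against more degraded RNA on arrays 1 and 2, but array 3 had the largest of all 5 arrays (1.32 and 1.33), so degraded RNA stays open for what array 3 adds. Fewer B cells in DBAxFVB F1 blood remains a hypothesis, as 2 of 3 arrays lay below both AKRxFVB F1 arrays and the remaining array between them, and a difference of genotype is untested; the 10 splits of 5 arrays are too few for a share under 0.05, with 7 lists in the real split and 8 in the highest other, and 3 splits, the real one included, gave as many.

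DBAxFVB F1 array 3 stood apart from the other arrays on the first principal component, which held 49% of the variance. Its hybridisation controls, labelled before they are added, lay -2.05 from the other arrays in the median, so a weak signal of the array itself is a candidate explanation. The tables argue against weak signal as the whole cause of its low platelet genes, since their median of -1.61 relative to the mean of the other 4 arrays lay at the 0.01 percentile of 10000 matched lists, the smallest possible. The matched lists had a median of -0.54 and a 2.5th percentile of -0.89, and the bootstrap interval over genes was -1.92 to -1.21. Degraded RNA in this sample stays open, given its 3-prime minus 5-prime differences above, loss of platelets or clotting before extraction was not tested, and no biological explanation was tested for a single sample.

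Genes at an unadjusted p below 0.01 were weighed against base differences between strains under single probe sets. For 358 such genes, 72.4% of 691 other probe sets of the same gene had the same sign (95% interval 68.9 to 75.7), against 50.7% of random pairs. The interval takes the probe sets as independent. Agreement was already 60.0% for genes that were not selected, so random pairs are too low a bar. Of 723 probe sets at that p, 617 were lower, and bright probe sets were lower as well, which can raise agreement by itself. The share therefore cannot decide whether base differences play a part. Agreement was 66.6% without the filter and 79.5% with the stricter one. Grouping along chromosomes, as inherited regulatory differences might give, stays open: 38.4% of 534 genes had another within 5 tested genes on either side (95% interval 34.2 to 42.7), against 35.5% in permutations (one-sided permutation p = 0.141 from 100000 resamples), and the p was 0.256 for 2 genes and 0.839 for 10. At an unadjusted p below 0.05 the real split gave 2337 probe sets, 1 of 10 splits with as many, and the highest other gave 1853; 10 splits are too few for a share under 0.05.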
